A study of Caenorhabditis elegans with 12 samples.

How the data were processed

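The series measured RNA from whole Caenorhabditis elegans hermaphrodites of 2 strains, the wild type N2 and the mutant unc-17(e245). The gene unc-17 encodes the transporter that loads acetylcholine into synaptic vesicles. Worms at the L4 larval stage had been kept at 20 C on NGM plates, were moved to new plates at 25 C, and were collected 24 hours later, per the labels' protocols and the series design text. The bacteria named are Escherichia coli OP50, the usual laboratory food, and Pseudomonas aeruginosa PA14, a pathogen of worms. RNA was extracted with a TransZol Up Plus kit and libraries were built with the NEBNext Ultra RNA kit, per the labels' protocols.

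The 12 libraries carry the titles ON, OU, PN and PU with a number from 1 to 3, which gives 4 groups of 3 libraries. The genotype field matches the last letter of each title (N for N2, U for unc-17(e245)). The treatment field reads OP50 for every ON and PN library and PA14 for every OU and PU library. That contradicts the leading letter if O and P stand for OP50 and PA14, and it contradicts the design text, in which both strains met both bacteria. Groups therefore followed the titles. The libraries are called O-titled and P-titled below, and no library is taken as infected or uninfected from its labels. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

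Per the submitters' processing notes, the authors used CASAVA, HISAT2 and featureCounts; their versions, the genome build, the annotation and the strand setting are not given in the sources used here. The deposited table is a signal per gene: read counts that the authors had divided by 1 factor per library. In each library the low values were whole multiples of the value of 1 read, which ranged from 0.788 to 1.42 between libraries, and dividing by it gave whole reads for 100.0% of values within 0.01 reads. For the library labelled OU 3 that value was 0.993, too near to 1 for the step to be told from unscaled counts by an automatic check; its recovered reads were used all the same. Recovered depth over the genes used was 14524565 to 18720808 reads per library. The lowest total over 12 libraries was 60 reads, so rarer genes had probably been filtered before deposit. The authors' factors were 0.991 to 1.01 times size factors computed here by the median-ratio method (RLE).

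Of the 15603 genes in the table, 488 had values shifted to the right by 1, 2 or 3 columns (468, 17 and 3 genes), because a comma inside the gene description had split it. Their values in the last libraries were lost. Read at face value they put identifiers into the ON 1 column and inflate its total. These genes were left out, which kept 15115 genes; 173 of the 488 have descriptions naming the mitochondrion. In an added alternative they were realigned and tested on the libraries they retain. Of the 15115 gene identifiers, 14572 were found in a table of current gene names and 13917 had the same symbol there; 684 had no symbol in the deposited table. Positions are not printed, since the build is not given. Exon lengths, used for the trend of fold change with length and for matched gene lists, came from the WBcel235 annotation.

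The test first planned was edgeR's quasi-likelihood test on counts. Because the deposited values are not counts, the main test became limma (trend, moderated) on log2(value + 1), fitted to all 12 libraries with 4 group means and 1 shared spread, with Benjamini-Hochberg adjustment over 15115 genes and a threshold of 0.05. A log2 fold change here is on the log2(value + 1) scale, which understates the change of low genes. The edgeR test on the recovered reads was run as an added alternative. The contrasts were OU minus ON and PU minus PN (strain), PN minus ON and PU minus OU (title letter), and their interaction. A separate limma fit compared the 6 N2 with the 6 unc-17(e245) libraries, which is also the split that the treatment field gives. R 4.3.3 was used with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.

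Gene lists, the tests first planned, the rule for named genes and most alternative settings were written down before the data were examined. The change of the main test to limma came later, from the form of the deposited values. The 33 lists covered p38 pathway components, p38 immune effectors, PA14-induced genes, C-type lectins, lysozymes, epidermal antimicrobial peptides, lysosomal proteins, the vacuolar ATPase, autophagy, Notch signalling, innexins, cholinergic signalling, DAF-16 targets, glutathione transferases, cytochromes P450 with UDP-glucuronosyltransferases, heat shock, hypoxia and cyanide, pals genes, fatty acid metabolism, yolk, collagens, sperm, oocyte and germline, embryo, intestine, body wall muscle, neurons, pharynx, gonadal sheath and spermatheca, neuropeptides, ribosomal proteins, histones and cell cycle. C49C8.5 had been entered as another name of irg-2 but is a gene of its own in the table. It counts as a member of the PA14-induced list. Some genes stand on several lists, so results of different lists are not independent. Among them, irg-4, irg-5 and clec-67 are on both the p38 immune effector and PA14-induced lists. The effectors lys-2 and gst-38 are also on the lysozyme and glutathione transferase lists, and the PA14-induced ilys-2 is on the lysozyme list. Each list was tested with camera, two-sided, with a preset correlation of 0.01, adjusted over the 33 lists of a contrast, and again with a correlation estimated from these libraries. No camera call in any of the 5 contrasts held with the estimated correlation. Those adjusted p are printed beside the calls. Where a range of adjusted p over alternatives is given for a list, it leaves out the estimated correlation. Genes with 0 reads in a whole group were also placed at their counting bound. In the 4 pairwise contrasts this moved a list median by at most 0.203, and it was not run for the interaction. Genes with a few reads in a group kept their estimates.

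The genes named are unc-17 and its locus partner cha-1; in each contrast the 6 largest rises and 6 largest falls past the threshold with a mean of at least 50 reads and no overlap between the groups; up to 4 members of each list with the smallest adjusted p; and in the interaction the 5 largest differences of each sign. Members of the p38, PA14-induced and Notch lists could be named freely. Histone, ribosomal RNA and mitochondrial genes appear only as groups. In a fold against 1 to 3 reads in a group the exact 95% counting interval is given, and against 0 reads a floor of 3 reads over the group; both cover counting error only. Near-identical copies (yolk genes vit-3, vit-4 and vit-5, the pud-1 and pud-2 pairs, major sperm proteins) may exchange reads, and unc-17 and cha-1 share a locus, so their separate values are uncertain.

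The calling step was tested on simulated counts for the 15115 genes with 200 changed genes and 1 dispersion, 0.0223, for all genes. Of genes changed 2-fold, 64.2% (OU minus ON), 67.2% (PU minus PN), 65.7% (PN minus ON) and 67.2% (PU minus OU) were called with the right sign; of those changed 1.5-fold, 29.9%, 13.4%, 23.9% and 26.9%; of those changed 4-fold, 95.5%, 93.9%, 93.9% and 95.5%. It called 10, 2, 7 and 2 unchanged genes. The alternative settings chosen then were other scalings (RLE, upper quartile), filters, DESeq2, limma voom, a replicate block, leaving out each library, a minimum fold of 2 and fits on the 6 libraries compared. Added after the data were seen were limma with TMM, RLE, upper-quartile and total-count scaling, the block in limma, pseudocounts of 0.5 and 5, a minimum mean of 50, leaving out OU 1 and PN 2 together, and the realigned genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.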

Results

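RNA-seq values of 15115 genes were compared between whole worms of 2 strains, N2 and unc-17(e245), in 4 title groups (ON, OU, PN and PU) of 3 libraries each. Depth was 15076764 to 15381746 reads in ON, 14524565 to 15431278 in OU, 16946650 to 18720808 in PN and 15814584 to 17639418 in PU. Across genes, the log2 values of libraries of the same group correlated at 0.975 to 0.99, and no library was a duplicate of another. The leading principal component held 54.7% of the variance and ordered the groups ON, OU, PN and PU, so it ran with both title letter and strain. The number of genes with 0 reads fell in the same order. It was 430 to 518 in ON, 124 to 213 in OU, 46 to 102 in PN and 17 to 35 in PU. Whether the component follows the groups themselves or the detection of rare genes was not tested. On the second component (17.6%), PN 2 lay at 44.22, apart from PN 1 (68.97) and PN 3 (69.36). The library labelled OU 1 held 6.86% of its reads in 5 ribosomal RNA genes, against 0.124% to 0.706% in the others. Yolk genes took 7.01% ± 1.16 of the reads in ON, 8.05% ± 0.485 in OU, 5.59% ± 0.219 in PN and 2.94% ± 0.143 in PU (SD, n = 3). Levels below are normalised reads as deposited, as mean ± SD with n = 3. A signed number with ± is a log2 fold change with its SE, and the median of a list is a median log2 fold change.

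The mutated gene was read first. unc-17 (WBGene00006756) stood at 47.7 ± 19.6 in ON, 55.9 ± 12.5 in OU, 32.7 ± 12.5 in PN and 101 ± 15.8 in PU. It was higher in PU than in PN (1.65 ± 0.34, limma adjusted p = 0.00159). Between OU and ON it did not pass the test (0.30 ± 0.34, limma adjusted p = 0.481), and without ON 2 the estimate was -0.10 (adjusted p = 0.813, 0.0733 to 0.813 over its alternatives). Its locus partner cha-1 (WBGene00000481), which encodes choline acetyltransferase, stood at 20.3 ± 7.89 in ON, 44.996 ± 11.28 in OU, 28.8 ± 8.06 in PN and 79.1 ± 6.64 in PU. It was higher in OU than in ON (1.15 ± 0.32, limma adjusted p = 0.00832) and in PU than in PN (1.46 ± 0.32, limma adjusted p = 0.00256). These levels do not check the strain labels, because e245 is not known here to lower the transcript and the pair may share reads.

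The design asks how the strains differ on each bacterium, and the series title names p38 signalling, Notch and the lysosome. In N2, the p38 immune effector and PA14-induced lists, which share genes such as irg-4 and irg-5, were higher under the P title. Lysozyme and C-type lectin genes went both ways. All 13 measured p38 immune effectors, genes known to depend on the kinase PMK-1, rose from ON to PN (median 4.89, camera adjusted p = 2.57e-11, and p = 0.157 with an estimated correlation). The infection response gene irg-5 went from 388 ± 73.7 to 187832 ± 21484 (8.93 ± 0.29) and irg-4 from 253 ± 11.7 to 10816 ± 1244 (5.41 ± 0.19). dod-24 (5.43 ± 0.11), the lysozyme gene lys-2 (4.89 ± 0.14) and sysm-1 (2.56 ± 0.16) rose as well. Of 20 measured PA14-induced genes, 16 rose and 2 fell (median 2.90, camera adjusted p = 1.7e-07, and p = 0.217 with an estimated correlation). Among them irg-1 went from 14.9 ± 16.6 to 1728 ± 63.9 (7.28 ± 0.46) and irg-3 from 209 ± 37.1 to 4487 ± 303 (4.43 ± 0.12). Of the 10 p38 pathway components 6 rose and 2 fell, without a list call (median 0.46, camera adjusted p = 0.202). The adaptor gene tir-1 (2.27 ± 0.20), the kinase gene pmk-1 (0.79 ± 0.11) and the phosphatase gene vhp-1 (1.78 ± 0.13) were among the rises.

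**Figure D1:**
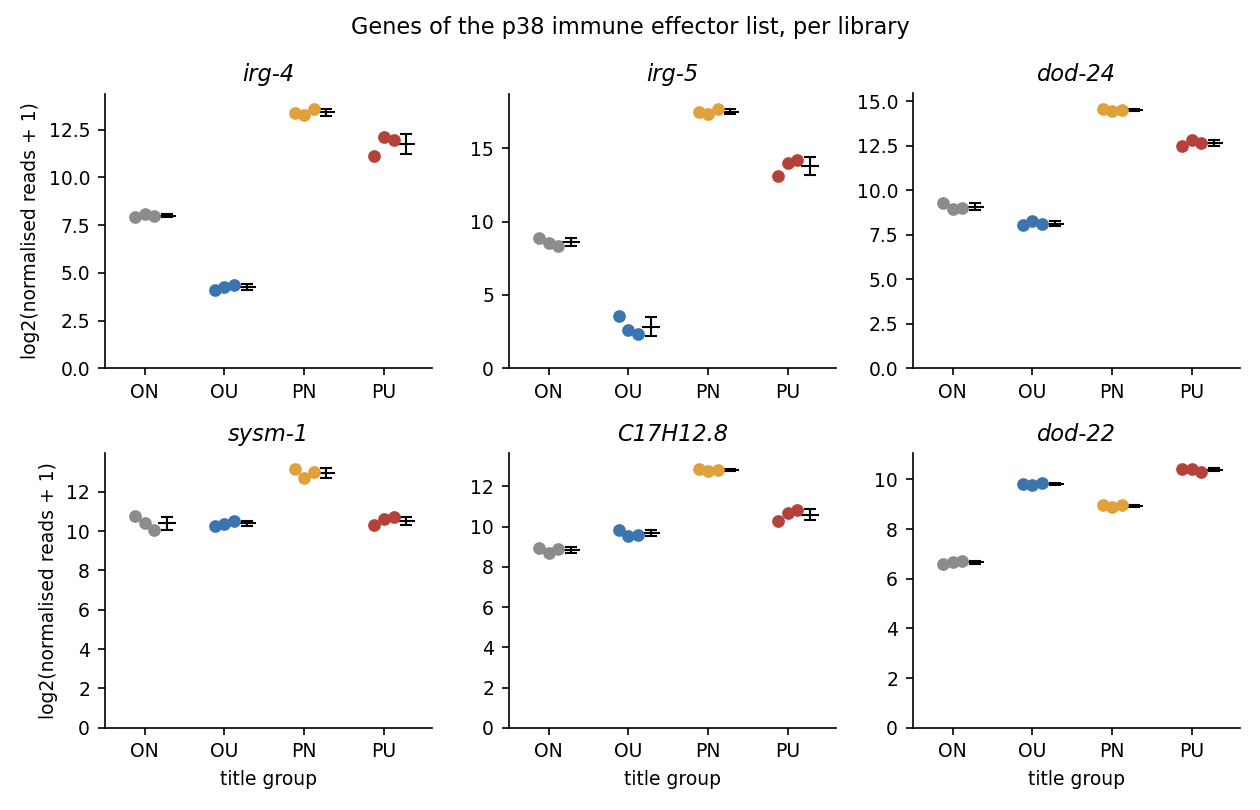
Normalised reads of 6 p38 immune effector genes, as log2(value + 1), in each of the 12 libraries by title group, with a dot per library and a bar for the mean ± SD of 3. All 3 PN libraries lie above all 3 ON libraries for each gene, and dod-22 stands higher in PU (1342 ± 60.9) than in PN (488 ± 16.9), unlike the other genes drawn.

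Several of the largest rises from ON to PN were in genes close to silent in ON, though irg-5 was not. C32H11.9 had 1.00 read over the ON libraries and 11271 over the PN libraries, a ratio of 6917 (95% counting interval 1281 to 281903). For dod-21 the ratio was 3622 (983 to 29340). B0024.4 rose (9.21 ± 0.15), and from 0 reads the P-glycoprotein gene pgp-7 rose at least 353-fold and F49H6.13 at least 377-fold. The C-type lectin genes clec-4 (7.37 ± 0.19) and clec-67 (6.77 ± 0.19) also rose. In the other direction acdh-1, an acyl-CoA dehydrogenase gene, went from 20066 ± 1943 to 1.40 ± 1.25 (-13.20 ± 0.36) and acdh-2 from 852 ± 138 to 1.14 ± 1.34 (-8.82 ± 0.60). The invertebrate lysozyme gene ilys-5 (-6.75 ± 0.14) fell, as did F15E6.4 (-6.44 ± 0.43), C09B8.4 (-6.44 ± 0.32) and F18E3.12 (-6.32 ± 0.92). The 13 lysozyme genes went both ways, 5 up and 7 down (median -2.58, camera adjusted p = 0.424). Of 18 pals genes, a family with members induced by microsporidia and viruses, 14 rose and none fell (median 1.86, camera adjusted p = 5.2e-04, and p = 0.0957 with an estimated correlation), led by pals-24 (4.06 ± 0.14) and pals-23 (3.96 ± 0.14). Of 124 cytochrome P450 and UDP-glucuronosyltransferase genes, 62 rose and 25 fell (median 0.89, camera adjusted p = 0.00972, and p = 0.619 with an estimated correlation), with rises of ugt-29 (3.57 ± 0.13) and cyp-13A12 (4.74 ± 0.23). Of 40 glutathione transferase genes 18 rose and 7 fell (median 0.54, camera adjusted p = 0.0386, and p = 0.644 with an estimated correlation), gst-38 up (8.03 ± 0.26) and gst-4 down (-2.27 ± 0.17).

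Oocyte, cell cycle, ribosomal protein, yolk and body wall muscle genes were lower in PN than in ON, while sperm genes were not called (13 up and 4 down of 56, median 0.53, camera adjusted p = 0.257). Of 28 oocyte and germline genes 27 fell (median -0.96, camera adjusted p = 2.23e-11, and p = 0.392 with an estimated correlation), such as the RNA helicase gene glh-1 (-1.51 ± 0.11) and the translational repressor gene gld-1 (-1.53 ± 0.14). Of 21 cell cycle genes 17 fell and 1 rose (median -0.57, camera adjusted p = 9.65e-06, and p = 0.383 with an estimated correlation), with falls of plk-1 (-0.91 ± 0.08) and mcm-2 (-1.15 ± 0.11). Ribosomal protein genes fell in 66 of 76 cases and rose in 2 (median -0.77, camera adjusted p = 6.89e-13, and p = 0.585 with an estimated correlation), for example rpl-20 (-1.06 ± 0.11) and rpl-28 (-0.95 ± 0.12). Of 6 yolk genes 5 fell (median -1.24, camera adjusted p = 0.00253, and p = 0.585 with an estimated correlation), vit-1 (-3.59 ± 0.18) and vit-3 (-3.63 ± 0.19) among them. Body wall muscle markers fell in 11 of 14 cases (median -0.89, camera adjusted p = 0.00148, and p = 0.619 with an estimated correlation), such as mlc-1 (-1.45 ± 0.13) and unc-27 (-1.55 ± 0.15). Collagen genes fell in 52 and rose in 18 of 157 cases (median -0.43, camera adjusted p = 0.00253, and p = 0.69 with an estimated correlation), with falls of col-181 (-2.26 ± 0.13) and col-122 (-2.41 ± 0.17), although the list median was 0.01 with total-count scaling. That scaling moved the median of all genes by 0.42, so the other list falls of this paragraph were smaller with it too, while their camera calls held.

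Genes of the vacuolar ATPase, which acidifies lysosomes, fell in 12 and rose in 1 of 21 cases (median -0.34, camera adjusted p = 0.00508, and p = 0.585 with an estimated correlation), vha-4 among them (-0.81 ± 0.10). With total-count scaling 7 rose and 2 fell and the call ended (adjusted p = 0.455, 5.71e-04 to 0.455 over its alternatives). Notch signalling genes fell in 12 and rose in 3 of 19 cases (median -0.41, camera adjusted p = 0.0323, and p = 0.585 with an estimated correlation), against 5 rises and 4 falls with total-count scaling. Of these lst-1 (-0.94 ± 0.11) and sel-10 (-0.67 ± 0.08) fell, and the receptor genes glp-1 (0.93 ± 0.10) and lin-12 (1.46 ± 0.20) rose. Neuron markers rose in 13 and fell in 3 of 18 cases (median 0.65, camera adjusted p = 0.022, and p = 0.619 with an estimated correlation), with rises of unc-13 (1.39 ± 0.21) and unc-64 (1.35 ± 0.10). Neuropeptide genes rose in 48 and fell in 7 of 127 cases (median 0.38, camera adjusted p = 0.022, and p = 0.688 with an estimated correlation), nlp-40 among the rises (1.15 ± 0.10). Intestine markers rose in 7 and fell in 3 of 12 cases, with ifd-2 (3.13 ± 0.13) and ifb-2 (2.45 ± 0.15) up, and the list missed the threshold (median 0.83, camera adjusted p = 0.0513).

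Limma called 4601 genes higher and 4101 lower in PN than in ON, and 3061 and 1142 of them changed at least 2-fold. At a minimum mean of 50 the split turned to 3074 higher and 3878 lower. With total-count scaling, which moved the median of all genes by 0.42, the split was 7335 and 1982. That scaling ended the camera calls of the Notch list (adjusted p = 0.123, 6.29e-04 to 0.123 over its alternatives) and of the P450 and glucuronosyltransferase list (0.112, 1.22e-04 to 0.112 over its alternatives). The glutathione transferase call ended with it (0.123), without ON 1 (0.082) and without PN 1 (0.0673, 3.86e-04 to 0.123 over its alternatives). The neuropeptide call ended without ON 2 (0.0686) or PN 1 (0.0742, 0.00609 to 0.0742 over its alternatives). unc-17 (-0.49 ± 0.34, limma adjusted p = 0.225) and cha-1 (0.52 ± 0.32, limma adjusted p = 0.182) did not pass the test. unc-17 passed it without ON 2 (0.0215, 0.0215 to 0.874 over its alternatives) and cha-1 with total-count scaling (0.0208, 0.0208 to 0.565 over its alternatives).

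In unc-17(e245) the title-letter contrast asks the same question of the mutant, and the p38 immune effector and PA14-induced lists were higher under the P title while lysozyme genes were lower. C-type lectin genes rose in 50 and fell in 38 of 127 cases (median 0.21, camera adjusted p = 0.825). Of 13 p38 immune effectors 11 rose and 1 fell from OU to PU (median 3.02, camera adjusted p = 1.72e-07, and p = 0.294 with an estimated correlation). irg-5 went from 6.57 ± 3.58 to 14944 ± 5457 (10.97 ± 0.29) and irg-4 from 18.05 ± 1.95 to 3582 ± 1176 (7.50 ± 0.19), and dod-24 (4.52 ± 0.11) and clec-4 (4.72 ± 0.19) rose. sysm-1 did not pass the test, at 1341 ± 126 in OU and 1488 ± 204 in PU (0.15 ± 0.16, limma adjusted p = 0.46). Of 20 PA14-induced genes 13 rose and 3 fell (median 2.29, camera adjusted p = 4.06e-05, and p = 0.294 with an estimated correlation), with rises of irg-1 (4.09 ± 0.46) and irg-3 (3.28 ± 0.12). In the p38 pathway list 7 of 10 rose, including tir-1 (1.78 ± 0.20) and the kinase gene sek-1 (0.71 ± 0.09), without a list call (median 0.57, camera adjusted p = 0.0648).

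Lysozyme genes fell in 9 and rose in 3 of 13 cases from OU to PU (median -3.19, camera adjusted p = 0.00366, and p = 0.294 with an estimated correlation). lys-10 went from 639 ± 234 to 1.77 ± 2.41 (-8.16 ± 0.72) and ilys-2 from 400.5 ± 67.8 to 1.20 ± 2.09 (-7.90 ± 0.53). ilys-3 (-6.73 ± 0.60), ilys-5 (-5.33 ± 0.14) and lys-4 (-4.92 ± 0.32) also fell, while lys-2 rose (3.02 ± 0.14). acdh-1 (-9.33 ± 0.36) and clec-47 (-5.83 ± 0.36) fell. mpst-2 had 437 reads in OU and 1.00 in PU, a ratio of 571 (95% counting interval 95.8 to 21240). Other large rises were F11D11.3 (7.46 ± 0.43) and Y46H3A.5 (7.18 ± 0.49). From 0 reads in OU, C01G10.4 rose at least 137-fold and pgp-7 at least 116-fold. The metallothionein gene mtl-1 went from 28.6 ± 12.7 to 2765 ± 1092 (6.54 ± 0.45) and the small heat shock gene hsp-12.6 rose (5.39 ± 0.36). Neither the DAF-16 target list (8 up and 3 down of 13, median 0.87, camera adjusted p = 0.089) nor the heat shock list (11 up and 3 down of 21, median 0.95, camera adjusted p = 0.159) was called.

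Sperm genes rose in 47 and fell in 3 of 56 cases (median 2.35, camera adjusted p = 1.13e-09, and p = 0.384 with an estimated correlation), with rises of msp-59 (2.70 ± 0.28) and msp-19 (2.86 ± 0.30). Of 28 oocyte and germline genes 27 fell (median -0.79, camera adjusted p = 7.76e-11, and p = 0.294 with an estimated correlation), such as egg-2 (-0.90 ± 0.08) and puf-5 (-0.90 ± 0.11). Of 21 cell cycle genes 19 fell (median -0.64, camera adjusted p = 9.28e-09, and p = 0.294 with an estimated correlation), rnr-2 (-1.02 ± 0.11) and plk-1 (-0.75 ± 0.08) among them. All 6 yolk genes fell (median -2.31, camera adjusted p = 2.33e-06, and p = 0.294 with an estimated correlation), with vit-3 (-5.54 ± 0.19) and vit-5 (-2.74 ± 0.19). Ribosomal protein genes rose in 64 of 76 cases with no fall (median 0.59, camera adjusted p = 1.21e-09, and p = 0.471 with an estimated correlation), including rpl-11.2 (1.90 ± 0.10) and rpl-25.1 (1.96 ± 0.12). Vacuolar ATPase genes fell in 16 of 21 cases (median -0.39, camera adjusted p = 1.92e-05, and p = 0.294 with an estimated correlation), vha-7 among them (-0.68 ± 0.08). Notch signalling genes fell in 11 and rose in 2 of 19 cases (median -0.46, camera adjusted p = 0.00445, and p = 0.294 with an estimated correlation), with falls of the protease gene sup-17 (-0.65 ± 0.09) and of lst-1 (-0.75 ± 0.11).

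Neuropeptide genes rose in 76 and fell in 7 of 127 cases from OU to PU (median 0.80, camera adjusted p = 1.72e-07, and p = 0.294 with an estimated correlation), with ins-20 (5.30 ± 0.48) and flp-17 (1.22 ± 0.13). Neuron markers rose in 11 of 18 cases (median 0.68, camera adjusted p = 0.00421, and p = 0.434 with an estimated correlation), egl-3 among them (1.56 ± 0.14). Pharynx markers rose in 9 of 13 cases (median 1.21, camera adjusted p = 4.15e-04, and p = 0.405 with an estimated correlation), such as phat-3 (1.77 ± 0.13) and pha-4 (1.58 ± 0.16). Intestine markers rose in 8 and fell in 2 of 12 cases without a call (median 0.84, camera adjusted p = 0.0836). Limma called 4598 genes higher and 3757 lower in PU than in OU, 3023 and 686 of them by at least 2-fold. With total-count scaling, which moved the median of all genes by 0.12, the split was 5244 and 2698. At a minimum mean of 50 it turned to 2788 higher and 3569 lower. unc-17 passed narrowly (0.86 ± 0.34, limma adjusted p = 0.0425). Its call ended without OU 2 (0.12), OU 3 (0.116), PU 1 (0.121) or PU 2 (0.1, 0.00898 to 0.121 over its alternatives). The cha-1 call (0.82 ± 0.32, limma adjusted p = 0.0397) ended without OU 2 (0.0987), OU 3 (0.136), PU 1 (0.0708), PU 2 (0.111) or PU 3 (0.0767, 0.00608 to 0.136 over its alternatives).

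Between the strains under P titles, the p38 immune effector and PA14-induced lists were lower in the mutant, while lysozyme and C-type lectin genes went both ways. Of 13 p38 immune effectors 12 fell and 1 rose from PN to PU (median -1.87, camera adjusted p = 1.68e-09, and p = 0.245 with an estimated correlation). irg-5 (-3.72 ± 0.29), gst-38 (-3.69 ± 0.26), C17H12.8 (-2.23 ± 0.13), dod-24 (-1.87 ± 0.11) and irg-4 (-1.65 ± 0.19) fell, and sysm-1 went from 8009 ± 1331 to 1488 ± 204 (-2.42 ± 0.16). dod-22 rose (1.46 ± 0.09). Of 20 PA14-induced genes 10 fell and 3 rose (median -0.65, camera adjusted p = 0.00654, and p = 0.508 with an estimated correlation), irg-7 among the falls (-1.89 ± 0.16). irg-1 was not called, at 956 ± 168 in PU and 1728 ± 63.9 in PN (-0.87 ± 0.46, limma adjusted p = 0.145). It was called without ON 3 (adjusted p = 0.00106, 1.27e-04 to 0.314 over its alternatives), by edgeR (0.00484) and by limma voom (1.27e-04). Intestine markers fell in 6 and rose in 4 of 12 cases (median -0.59, camera adjusted p = 0.0419, and p = 0.329 with an estimated correlation), with the brush border actin gene act-5 (-1.86 ± 0.12) and ifd-2 (-2.06 ± 0.13) down and the metallothionein gene mtl-2 up (3.74 ± 0.41). In the p38 pathway list 4 of 10 rose and none fell (median 0.06, camera adjusted p = 0.384). Lysozyme genes went both ways, 4 up and 4 down of 13 (median 0.69, camera adjusted p = 0.945), with falls of lys-1 (-1.66 ± 0.11) and lys-8 (-1.66 ± 0.10), and C-type lectin genes had 40 rises and 39 falls of 127 (median -0.02, camera adjusted p = 0.656).

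Among the largest falls from PN to PU, pud-3 went from 991 ± 244 to 7.89 ± 6.23, and pud-2.1 (-4.54 ± 0.40), pud-1.1 (-4.53 ± 0.40), pud-4 (-4.40 ± 0.28), F49H6.13 (-4.59 ± 0.44) and clec-125 (-4.54 ± 0.46) fell. D1086.9 rose at least 199-fold from 0 reads, and C54F6.6 (6.45 ± 0.48), C54F6.15 (6.16 ± 0.35), scl-14 (6.10 ± 0.42), T23F2.4 (5.34 ± 0.51) and mtl-1 (5.26 ± 0.45) rose. DAF-16 targets, genes under insulin signalling, rose in 8 and fell in 3 of 13 cases (median 1.15, camera adjusted p = 0.0135, and p = 0.536 with an estimated correlation), and daf-16 itself rose (1.15 ± 0.12). Heat shock genes rose in 14 and fell in 2 of 21 cases (median 1.38, camera adjusted p = 0.00654, and p = 0.536 with an estimated correlation), with hsp-12.6 (3.96 ± 0.36) and hsp-6 (0.73 ± 0.11) up and hsp-17 down (-0.95 ± 0.12). Neuropeptide genes rose in 69 and fell in 10 of 127 cases (median 0.81, camera adjusted p = 3.47e-11, and p = 0.329 with an estimated correlation), with nlp-9 (3.04 ± 0.11) and flp-18 (2.62 ± 0.11). Neuron markers rose in 9 and fell in 2 of 18 cases (median 0.65, camera adjusted p = 7.46e-04, and p = 0.464 with an estimated correlation), with egl-3 (1.80 ± 0.14) and ida-1 (2.06 ± 0.19). Cholinergic signalling genes rose in 13 and fell in 1 of 38 cases (median 0.77, camera adjusted p = 0.00178, and p = 0.464 with an estimated correlation), the muscarinic receptor gene gar-3 among the rises (1.38 ± 0.28). Pharynx markers rose in 11 of 13 cases (median 1.78, camera adjusted p = 5.33e-07, and p = 0.332 with an estimated correlation), with phat-3 (1.78 ± 0.13) and phat-6 (1.96 ± 0.15).

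Vacuolar ATPase genes fell in 20 of 21 cases from PN to PU (median -0.59, camera adjusted p = 9.14e-11, and p = 0.245 with an estimated correlation), such as vha-6 (-1.01 ± 0.11) and vha-12 (-0.98 ± 0.11). The list of lysosomal genes was not called, with 12 rises and 16 falls of 43 (median -0.151, camera adjusted p = 0.3645). Of 6 yolk genes 5 fell (median -1.98, camera adjusted p = 3.13e-06, and p = 0.329 with an estimated correlation), with vit-3 (-3.78 ± 0.19) and vit-4 (-4.14 ± 0.16). Glutathione transferase genes fell in 18 and rose in 5 of 40 cases (median -0.57, camera adjusted p = 2.24e-04, and p = 0.464 with an estimated correlation), gst-4 among the falls (-1.92 ± 0.17). Sperm genes rose in 28 and fell in 1 of 56 cases (median 1.01, camera adjusted p = 5.49e-06, and p = 0.536 with an estimated correlation), with msp-59 (1.35 ± 0.28), gsp-3 (1.81 ± 0.38) and spe-15 (1.21 ± 0.16). Ribosomal protein genes rose in 34 of 76 cases with no fall (median 0.28, camera adjusted p = 6.9e-06, and p = 0.667 with an estimated correlation), such as rpl-24.2 (0.89 ± 0.11) and rpl-4 (0.60 ± 0.14). Cell cycle genes fell in 8 of 21 cases (median -0.15, camera adjusted p = 0.0145, and p = 0.536 with an estimated correlation), air-2 among them (-0.40 ± 0.08). Notch signalling genes fell in 7 of 19 cases without a list call (median -0.18, camera adjusted p = 0.0627), among them aph-2 (-0.58 ± 0.11). Limma called 3010 genes higher and 2800 lower in PU than in PN, 1891 and 869 of them by at least 2-fold. The split was 3798 and 1912 with total-count and 3553 and 2194 with upper-quartile scaling. It turned to 2766 higher and 3361 lower with TMM scaling in limma, and to 1864 and 2571 at a minimum mean of 50. The camera call of intestine markers ended without ON 1 (adjusted p = 0.0599) or PU 3 (0.0598, 1.71e-05 to 0.0599 over its alternatives). That of the cell cycle list ended with upper-quartile (0.0582) or total-count scaling (0.1, 0.00333 to 0.1 over its alternatives).

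Between the strains under O titles, p38 immune effectors went both ways and lysozyme genes were higher in the mutant. Of 13 p38 immune effectors 6 rose and 5 fell from ON to OU (median -0.01, camera adjusted p = 0.939), a median whose sign changed between scalings. irg-5 (-5.76 ± 0.29) and irg-4 (-3.74 ± 0.19) fell, and dod-22 (3.15 ± 0.09) and clec-67 (2.87 ± 0.19) rose. Of 20 PA14-induced genes 10 rose and 6 fell (median 0.39, camera adjusted p = 0.28), with rises of clec-60 (5.77 ± 0.43) and irg-1 (2.32 ± 0.46). Lysozyme genes rose in 9 and fell in 2 of 13 cases (median 1.47, camera adjusted p = 0.0132, and p = 0.628 with an estimated correlation). lys-10 went from 12.04 ± 14.1 to 639 ± 234 and ilys-2 from 10.9 ± 2.95 to 400.5 ± 67.8 (5.09 ± 0.53). ilys-3 had 1.00 read over the ON libraries and 642 in OU, a ratio of 528 (95% counting interval 87.03 to 19251). Lysosomal genes went both ways, 13 up and 13 down of 43 (median 0.05, camera adjusted p = 0.415), with the protease gene cpr-3 (3.28 ± 0.13) and the lipase gene lipl-2 (3.43 ± 0.17) up. With total-count scaling 25 of them rose and 3 fell. Epidermal antimicrobial peptide genes fell in 8 of 15 cases (median -0.78, camera adjusted p = 0.0157, and p = 0.628 with an estimated correlation), such as nlp-27 (-1.77 ± 0.22) and cnc-3 (-1.52 ± 0.21). Of 18 pals genes 11 rose (median 1.25, camera adjusted p = 8.56e-04, and p = 0.107 with an estimated correlation), with pals-24 (1.31 ± 0.14) and pals-23 (1.29 ± 0.14).

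Outside these lists, C54F6.15 had 1.00 read in ON and 586 in OU, a ratio of 429 (95% counting interval 79.4 to 17574). Y39G8B.9 (6.75 ± 0.33) and R08F11.4 (6.28 ± 0.47) rose, the latter to 824 ± 666 in OU. Y48E1B.8 (-6.43 ± 0.56), F42A10.7 (-5.56 ± 0.30), acdh-2 (-5.55 ± 0.60), F46F2.3 (-5.21 ± 0.30) and pud-3 (-4.53 ± 0.37) had the largest falls beside irg-5. All 76 ribosomal protein genes fell (median -1.01, camera adjusted p = 1.15e-27, and p = 0.515 with an estimated correlation), for example rpl-31 (-1.32 ± 0.13) and rpl-28 (-1.21 ± 0.12). Vacuolar ATPase genes fell in 18 and rose in 2 of 21 cases (median -0.61, camera adjusted p = 4.16e-06, and p = 0.515 with an estimated correlation), with vha-14 (-0.78 ± 0.09) and vha-4 (-0.89 ± 0.10) down. Of 6 yolk genes 4 fell (median -1.22, camera adjusted p = 0.0157, and p = 0.628 with an estimated correlation), vit-1 (-3.63 ± 0.18) and vit-4 (-1.88 ± 0.16) among them. Together yolk genes still took 8.05% of the reads in OU against 7.01% in ON, so the median fall does not mean a smaller yolk share. Sperm genes fell in 23 of 56 cases (median -0.75, camera adjusted p = 0.00299, and p = 0.722 with an estimated correlation) and embryo genes in 8 of 15 (median -0.58, camera adjusted p = 0.0189, and p = 0.628 with an estimated correlation). Oocyte and germline genes fell in 17 of 28 cases (median -0.33, camera adjusted p = 7.39e-04, and p = 0.628 with an estimated correlation), such as glh-1 (-0.97 ± 0.11) and gld-1 (-1.01 ± 0.14), but with total-count scaling 7 rose and 2 fell. Glutathione transferase genes fell in 16 and rose in 6 of 40 cases (median -0.46, camera adjusted p = 0.0458, and p = 0.628 with an estimated correlation), gst-4 among the falls (-3.52 ± 0.17), but with total-count scaling 10 rose and 8 fell. That scaling moved the median of all genes by 0.40, so the other list falls of this paragraph were smaller with it too.

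Neuropeptide genes rose in 54 and fell in 13 of 127 cases from ON to OU (median 0.48, camera adjusted p = 5.23e-04, and p = 0.628 with an estimated correlation), with flp-18 (2.66 ± 0.11) and nlp-21 (2.53 ± 0.12). Neuron markers rose in 11 and fell in 2 of 18 cases (median 0.66, camera adjusted p = 0.00228, and p = 0.628 with an estimated correlation), with unc-13 (1.86 ± 0.21) and the kinesin gene unc-104 (1.56 ± 0.17). Pharynx markers rose in 8 and fell in 1 of 13 cases (median 0.77, camera adjusted p = 0.0101, and p = 0.628 with an estimated correlation), phat-3 among the rises (1.51 ± 0.13). Cholinergic signalling genes rose in 13 and fell in 2 of 38 cases (median 0.69, camera adjusted p = 0.0231, and p = 0.628 with an estimated correlation). In the Notch list 3 of 19 rose and 10 fell without a call (median -0.30, camera adjusted p = 0.161), with glp-1 up (1.22 ± 0.10) and osm-11 down (-0.87 ± 0.13), and with total-count scaling 8 rose and 3 fell. The chaperone gene hsp-70 went from 66.6 ± 21.95 to 1327 ± 325 (4.32 ± 1.13), while the heat shock list had 4 rises and 6 falls of 21 (median 0.40, camera adjusted p = 0.941), or 7 rises and no fall with total-count scaling.

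Limma called 3558 genes higher and 3666 lower in OU than in ON, 1909 and 971 of them by at least 2-fold. With total-count scaling, which moved the median of all genes by 0.40, the split was 6625 and 1238. Total-count scaling ended the camera calls of the cholinergic list (adjusted p = 0.235, 0.0118 to 0.235 over its alternatives) and of the germline list (0.235, 1.01e-05 to 0.235 over its alternatives). Without OU 1, the library rich in ribosomal RNA, the cholinergic (0.0638) and glutathione transferase calls (0.0606, 0.00662 to 0.115 over its alternatives) ended. They ended without ON 2 too (0.0682 and 0.115), and the latter without ON 3 (0.112).

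**Figure D2:**
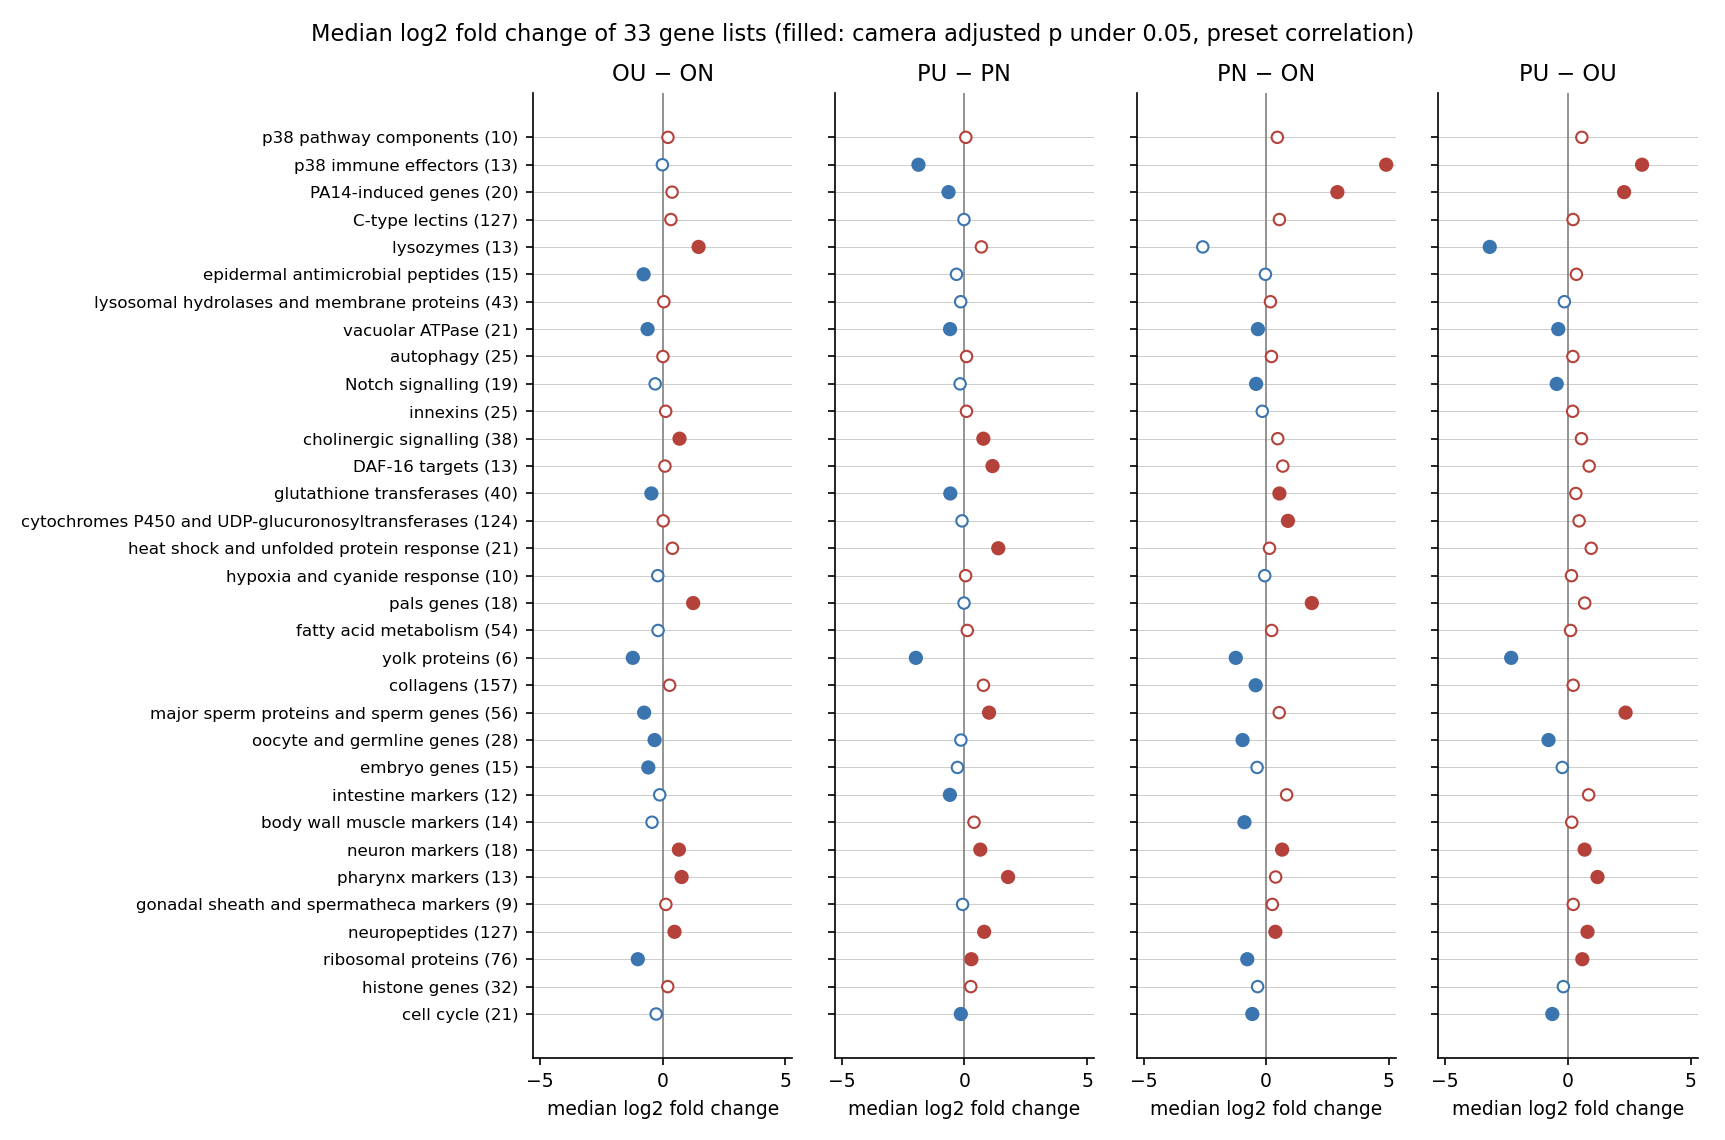
Median log2 fold change of each of the 33 gene lists (number of genes tested in brackets) in the 4 pairwise contrasts, with filled dots for lists that passed camera with the preset correlation, open dots for the others, and red above and blue below 0. p38 immune effectors stand at 4.89 in PN minus ON, 3.02 in PU minus OU and -1.87 in PU minus PN, and with total-count scaling the medians of the vacuolar ATPase, Notch and collagen lists in PN minus ON and of the germline list in OU minus ON turn positive.

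Several lists were called in none of these 4 contrasts. One is that of lysosomal genes, with 17 rises and 15 falls of 43 from ON to PN (median 0.174, camera adjusted p = 0.974). From OU to PU it had 11 rises and 19 falls (median -0.145, camera adjusted p = 0.0634). C-type lectin genes rose in 48 and fell in 24 of 127 cases from ON to OU (median 0.34, camera adjusted p = 0.119), and in 46 and 35 cases from ON to PN (median 0.54, camera adjusted p = 0.31). From ON to PN, autophagy genes rose in 10 and fell in 7 of 25 cases (median 0.22, camera adjusted p = 0.306), and innexins in 6 and 7 of 25 (median -0.16, camera adjusted p = 0.604), or in 11 and 3 with total-count scaling. In that contrast, hypoxia and cyanide genes rose in 4 and fell in 2 of 10 cases (median -0.06, camera adjusted p = 0.974), a median that turned positive with 3 scalings. Fatty acid metabolism genes rose in 18 and fell in 17 of 54 cases (median 0.23, camera adjusted p = 0.827), and gonadal sheath and spermatheca markers rose in 3 of 9 (median 0.25, camera adjusted p = 0.103). Histone genes rose in 4 and fell in 9 of 32 cases (median -0.35, camera adjusted p = 0.174), or in 6 and 4 with total-count scaling.

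Adjusted over the list alone, the numbers of rises and falls were those given above for 18 of the 33 lists in OU minus ON, 21 in PU minus PN, 24 in PN minus ON and 19 in PU minus OU. The largest shift was of 7 genes, with 35 sperm genes higher in PU minus PN and 5 cholinergic genes higher in place of 12 in PU minus OU. List medians are not adjusted for gene length or level, with which the fold changes of all genes moved. Spearman correlations across genes, which are not independent replicates, were 0.202 with exon length in OU minus ON, 0.066 in PU minus PN, 0.077 in PN minus ON and -0.034 in PU minus OU. With mean level they were -0.267, -0.316, -0.409 and -0.456 in that order. Genes of up to 500 bases had a median of -0.37 in OU minus ON and -0.01 in PN minus ON, and those over 5000 bases one of 0.54 and 0.60. All 73 called list results, interaction included, had median, mean and tests of the same sign, and 31 of all 165 list results did not.

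The interaction asks whether the strain difference depended on the title letter. Ribosomal protein genes had a positive interaction in 74 of 76 cases (median 1.33, camera adjusted p = 4.01e-33, and p = 0.42 with an estimated correlation), such as rpl-31 (1.75 ± 0.19) and rps-6 (1.49 ± 0.16). p38 immune effectors were negative in 10 and positive in 2 of 13 cases (median -1.87, camera adjusted p = 4.93e-06, and p = 0.42 with an estimated correlation). sysm-1 (-2.41 ± 0.23), C17H12.8 (-3.06 ± 0.18), clec-67 (-4.29 ± 0.28) and dod-22 (-1.69 ± 0.13) were negative, while irg-4 (2.09 ± 0.27) and irg-5 (2.04 ± 0.41), already lower in OU than in ON, were positive. Among PA14-induced genes irg-7 (-2.75 ± 0.23) and irg-1 (-3.19 ± 0.65) were negative. The Notch receptor genes glp-1 (-0.99 ± 0.14) and lin-12 (-0.97 ± 0.28) and pals-24 (-1.75 ± 0.20) were negative, and sek-1 (0.71 ± 0.13) and daf-16 (1.07 ± 0.16) positive. F56C3.9 (-7.68 ± 0.61), R08F11.4 (-7.32 ± 0.66) and tsp-1 (-6.17 ± 0.49) had large negative values. ilys-3 and F49H6.13 were negative too, but ilys-3 had 0 reads in PN and F49H6.13 had 0 in ON, so the size of their interactions depends on the pseudocount and is not given a rank. That of acdh-2 was positive, but its levels were near 0 in PN (1.14 ± 1.34) and PU (4.67), so its size depends on the pseudocount too. Large positive values were those of mtl-2 (6.38 ± 0.58), col-81 (4.96 ± 0.84), F42A10.7 (4.92 ± 0.42) and mtl-1 (4.82 ± 0.64).

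Limma called the interaction for 4882 genes, 2516 positive and 2366 negative, or 1286 and 3949 with total-count scaling. The ilys-3 interaction was not called by edgeR (adjusted p = 0.954, 3.76e-06 to 0.954 over its alternatives) and that of irg-5 not by limma voom (0.0862, 1.81e-04 to 0.0862 over its alternatives). cha-1 had none past the test (0.31 ± 0.45, limma adjusted p = 0.638). That of unc-17 (1.35 ± 0.48, limma adjusted p = 0.0416) ended without ON 1 (0.0908), ON 3 (0.0979), OU 2 (0.0866), OU 3 (0.0822), PN 1 (0.0992), PN 3 (0.0901), PU 1 (0.0897) or PU 2 (0.0819, 0.0043 to 0.0992 over its alternatives).

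**Figure D3:**
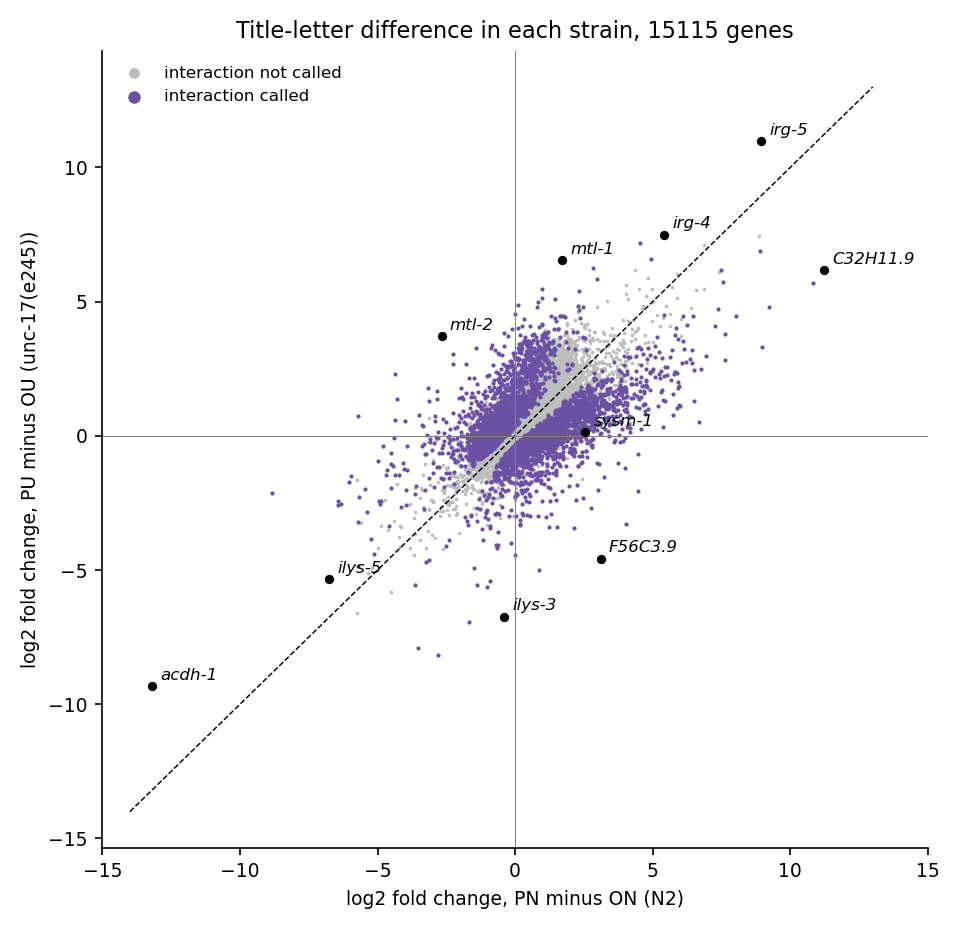
Log2 fold change of PU minus OU in unc-17(e245) against that of PN minus ON in N2 for 15115 genes, with genes called in the interaction in purple, others in grey and the line of equal change dashed. acdh-1 lies far down in both contrasts (-13.20 and -9.33), and irg-5 far up in both (8.93 and 10.97).

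The title-letter contrasts, which share no library, called 2697 genes higher in both strains and 2366 lower in both, against 1400 and 1019 for independent lists of those sizes. Another 294 and 251 genes were called in opposite directions. Log2 fold changes correlated at 0.63 (Pearson) and 0.636 (Spearman) across genes, which are not independent replicates. The strain contrasts shared 1242 higher and 1112 lower genes, against 709 and 679 (one-sided Fisher's exact test, p = 2.63e-132 and 1.13e-91), with 513 and 379 in opposite directions, and correlated at 0.416 (Pearson) and 0.347 (Spearman) across genes. Fisher's test takes genes as independent, which they are not, so its p-values do not measure how well the strain difference would repeat. With total-count scaling the strain contrasts shared 2120 higher and 412 lower genes, and the title-letter contrasts 3868 and 1044. flp-18 and phat-3 rose and vit-4 and gst-4 fell in the mutant under both letters.

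The split that the genotype and treatment fields give on their own sets 6 N2 against 6 unc-17(e245) libraries and mixes the title letters. Limma called 943 genes higher and 725 lower in the mutant, or 1448 and 322 with total-count scaling. The total of 1668 ignores the title letter, and it was 5629 with the letter as a covariate, 2871 with DESeq2, 1041 at a minimum mean of 50 and 758 with edgeR and a strict filter. It became 1103 without ON 1, 939 without ON 2, 1037 without ON 3, 883 without PU 1, 866 without PU 2 and 893 without PU 3.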

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

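The regroupings of libraries, the tests of the 3 patterns weighed and, for lists, leaving out single libraries were chosen only after the results had been seen. The planned edgeR test with TMM scaling had been replaced by limma as the main test and was kept as an alternative. The results in this part were singled out because the strain difference was not the same under P titles as under O titles, by a test of that difference itself (the interaction). It was called for 4882 genes (limma, 12 libraries). Among 100 drawings of the 12 libraries into 4 groups of 3, 2 called as many genes, the real one included, and the highest other called 6170. The drawings mix strains and title letters, and the median SD within drawn groups was 2.23 times that within the real ones (0.548 against 0.245), so they do not test whether chance gives such an interaction.

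Among the genes named for large interactions, the negative ones were F56C3.9 (-7.68 ± 0.61), R08F11.4 (-7.32 ± 0.66), the lysozyme gene ilys-3 (-6.34 ± 0.85), the tetraspanin gene tsp-1 (-6.17 ± 0.49) and F49H6.13 (-5.67 ± 0.62). The positive ones were acdh-2 (6.71 ± 0.85), the metallothionein genes mtl-2 (6.38 ± 0.58) and mtl-1 (4.82 ± 0.64), the collagen gene col-81 (4.96 ± 0.84) and F42A10.7 (4.92 ± 0.42). ilys-3 had 0 reads in PN and F49H6.13 had 0 in ON, and acdh-2 was near 0 in PN and PU, so the sizes of these 3 interactions depend on the pseudocount and give no rank. edgeR did not call ilys-3 (adjusted p = 0.954, 3.76e-06 to 0.954 over its alternatives).

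Of the 33 lists, 16 were called by camera with the preset correlation and none with an estimated one. Negative medians were found for p38 immune effectors (median -1.87, camera adjusted p = 4.93e-06), PA14-induced genes (median -1.27, camera adjusted p = 0.0118), lysozymes (median -1.63, camera adjusted p = 0.0118), pals genes (median -1.13, camera adjusted p = 0.00596) and yolk genes (median -1.39, camera adjusted p = 0.0225). Lysosomal genes (median -0.32, camera adjusted p = 0.0374), intestine markers (median -0.37, camera adjusted p = 0.0436) and gonadal sheath and spermatheca markers (median -0.34, camera adjusted p = 0.0487) were negative too. Positive medians were found for ribosomal proteins (median 1.33, camera adjusted p = 4.01e-33), sperm genes (median 1.80, camera adjusted p = 1.45e-08), body wall muscle markers (median 0.92, camera adjusted p = 0.00124), DAF-16 targets (median 0.78, camera adjusted p = 0.0084), heat shock genes (median 1.22, camera adjusted p = 0.0301), pharynx markers (median 0.52, camera adjusted p = 0.0152), neuropeptides (median 0.43, camera adjusted p = 0.00706) and collagens (median 0.36, camera adjusted p = 0.0427). With the estimated correlation the adjusted p ran from 0.234 for pals genes to 0.901 for collagens. In 100 drawings of the libraries, 4 called at least 16 lists, the real one included, and the highest other number was 16. These drawings mix strains and title letters in the same way, so they do not test chance for the lists either.

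Some of these list calls rest on few libraries. The ranges over alternatives leave out the estimated correlation, with which none was called. The lysosomal call ended without ON 2 (adjusted p = 0.103) or PN 1 (0.0796, 0.0174 to 0.103 over its alternatives), and the heat shock call without ON 2 (0.0535) or PN 1 (0.119, 0.00679 to 0.119 over its alternatives). The intestine call ended without ON 1 (0.0519), ON 2 (0.0748), OU 3 (0.0652), PN 1 (0.0721), PN 3 (0.0513) or PU 3 (0.0561, 3.15e-04 to 0.0748 over its alternatives). The collagen call ended without ON 1 (0.0519), ON 2 (0.0748), OU 2 (0.0567), OU 3 (0.096), PN 1 (0.132), PN 3 (0.282), PU 2 (0.105) or PU 3 (0.0909, 4.24e-05 to 0.388 over its alternatives). The gonadal sheath call ended without ON 2 (0.0881), ON 3 (0.0587), OU 2 (0.0781), PN 2 (0.0649), PN 3 (0.0583), PU 2 (0.0622) or PU 3 (0.0512, 0.0152 to 0.0881 over its alternatives).

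The pairwise contrasts were regrouped as well, but 6 libraries make only 10 splits into 3 and 3, too few for a share under 0.05. In OU minus ON, 1 split (the real one) called as many as 7224 genes and the highest other called 0 (limma, adjusted p). In PU minus PN, 1 split called as many as 5810 and the highest other called 16. In PN minus ON, 1 split called as many as 8702 and the highest other called 0, and in PU minus OU, 1 split called as many as 8355 and the highest other 0. Lists called by camera were less particular to the real split. As many lists as in the real split were called in 1 of 10 splits for OU minus ON (14, highest other 13), 2 for PU minus PN (15, highest other 16), 2 for PN minus ON (15, highest other 15) and 4 for PU minus OU (13, highest other 13). In the split of 6 N2 against 6 unc-17(e245) libraries, 3 of 100 drawn splits called as many as 1668 genes, the real one included. The libraries form tight groups, so a split that keeps groups whole calls many genes whatever the strain does, and these splits do not test chance. The highest other called 5311 and the split by title letter 7288, several times the real number, which points to a structure of the samples that follows the groups.

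The first pattern weighed is what the P title stands for, since the treatment field and the titles disagree. If the treatment field were right, ON and PN would both be N2 on OP50, yet 16 of 20 PA14-induced genes were higher in PN than in ON, which argues against it. A single library exchanged between O and P titles is argued against too. In the mean log2 of that list, 6 of 6 P-titled libraries lay above all O-titled libraries (8.65 to 9.60 against 6.115 to 7.08). This does not test an exchange between the strains within a title letter. Library scaling left 16 of the genes higher in each of 5 scalings. A candidate explanation is that P stands for PA14, although other differences between the plates, such as another bacterium, were not tested.

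The next pattern is the lower level of p38 immune effectors in PU than in PN. Library scaling is argued against as its cause, as at least 12 of 13 effectors were lower in each of 5 scalings. Less intestinal RNA in PU could lower them too: intestine markers had a median of -0.592, which is 1.28 above the effectors' -1.873. The markers moved both ways, with 6 down and 4 up of 12. Their SD of 1.52 is a spread between genes, not the error of a median. The difference between the medians therefore does not settle whether less intestinal RNA or a change within the intestine lowered the effectors. In the interaction 10 of 13 effectors were negative and 2 positive. The positive ones, irg-4 and irg-5, were already lower in OU than in ON. Their log2 rises with the P title were larger in the mutant, so a smaller rise does not account for their lower level in PU. For the others a weaker response of unc-17(e245) worms, which the design names, stays open beside less intestinal RNA and was not tested apart from it.

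The last pattern is the lower level of ribosomal protein genes in OU and in PN than in ON. In OU minus ON, lists matched on gene length and level had a median of -0.844 (95% range -0.946 to -0.699) against the observed -1.012. Matched genes thus fell by most of it. The matched lists drew on only 162 different genes and ignored correlation between genes, estimated at 0.522 for the ribosomal protein list. Their range is therefore probably too narrow to decide whether length and level are the whole cause. In PN minus ON the matched range (-0.91 to -0.70, median -0.822) covers the observed -0.77, so the matched genes fell about as much. Short genes as a whole did not fall there (median -0.01 up to 500 bases), while fold changes of all genes ran with level (Spearman -0.409). Ribosomal RNA in the library labelled OU 1 is argued against, since 73 of 76 genes were lower without it, and so is library scaling, with at least 63 lower in OU and 43 lower in PN over 5 scalings. A difference of strain or title letter in growth stays open, untested.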

How the results depend on the processing

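The edgeR test with TMM scaling was the test first planned and became an alternative when limma replaced it. Other scalings in limma, the limma block, pseudocounts and the minimum mean of 50 were chosen only after the data had been seen. So were the joint omission of OU 1 and PN 2, the realigned genes and, for the list tests, leaving out single libraries. Of 217 named gene results, 208 kept their direction and their side of the threshold in all 23 alternatives checked gene by gene. Of 4991 values 4960 did, with 24 weaker, 6 stronger and 1 reversed. Named genes were not checked in the edgeR runs with RLE or upper-quartile scaling, without a filter or with the strict filter. Nor were they checked at the minimum mean of 50, in the joint omission or in the fits on the 6 libraries compared. The reversed value was unc-17 in OU minus ON, not called in either case, at -0.10 without ON 2 against 0.30, and 0.51 without ON 3. Of 1387 values of the 73 called list results, 1265 stayed called, and 73 of the others came from the estimated correlation.

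With edgeR (TMM) 6998 genes were called in OU minus ON, 6211 in PU minus PN, 8509 in PN minus ON, 8297 in PU minus OU and 4919 in the interaction, and it kept 92.6%, 96.8%, 95.9%, 94.7% and 93.9% of the limma calls with the same sign. Leaving out each library gave 5836 to 7240, 4097 to 6341, 7941 to 8746, 7025 to 8761 and 4047 to 5283 genes in that order. For the split of 6 against 6 it gave 866 to 1982. For shared calls it gave 948 to 1283 (strain, higher), 776 to 1221 (strain, lower), 2336 to 2757 (title letter, higher) and 1976 to 2454 (title letter, lower). Lists called ran from 13 to 15, 14 to 18, 13 to 16, 13 to 15 and 12 to 18. Without OU 1 and PN 2 together 5880, 5604, 7990, 8264 and 4475 genes were called.

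A minimum fold of 2 lowered the counts by construction, to 2880 in OU minus ON, 2760 in PU minus PN, 4203 in PN minus ON, 3709 in PU minus OU and 2308 in the interaction. The strict filter with edgeR, which tests fewer genes, called 3710 in PU minus PN, 4859 in PU minus OU and 758 in the split of 6 against 6. That split called 868 genes with the edgeR block, 865 with the limma block, 1041 at a minimum mean of 50, 2871 with DESeq2 and 5629 with the title letter as a covariate. For these the cause was not tested, apart from the covariate, which removes the title-letter spread.

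Strain calls shared and higher numbered 744 at an absolute log2 of at least 1, 806 with the strict filter, 815 at a minimum mean of 50 and 2120 with total-count scaling. Those shared and lower numbered 232, 639 (strict filter) and 412 (total-count). Title-letter calls shared and higher numbered 1634 at an absolute log2 of at least 1, and those shared and lower 305, 1311 with the strict filter and 1044 with total-count scaling. Total-count scaling moves the median of all genes upward in each of the 4 pairwise contrasts these counts rest on. In the interaction it gave 1286 positive and 3949 negative calls against 2516 and 2366.

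Among list tests, camera with an estimated correlation called 0 lists in each of the 5 contrasts, against 26 in PN minus ON and 24 in PU minus OU with fry, which asks another question. fry did not call sperm genes in OU minus ON (adjusted p = 0.0933, 5.61e-06 to 0.0933 over its alternatives), or heat shock genes (0.0906), collagens (0.388) and pharynx markers (0.0643, 0.00138 to 0.0643 over its alternatives) in the interaction. The numbers 1 to 3 do not pair libraries: correlations of 18 pairs with the same number ran from -0.138 to 0.23, and 4 of 12 libraries correlated best with their own number. With the number as a block limma called 7008, 5565, 8573, 8192 and 4616 genes. The block ended the unc-17 (0.0542) and cha-1 (0.055) calls in PU minus OU, the unc-17 interaction (0.0553) and the gonadal sheath list of the interaction (0.0512). Total-count scaling ended the unc-17 interaction too (0.0866).

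With 3 libraries per group at this depth, 64.2% to 67.2% of simulated 2-fold changes were called, so smaller changes can be missed. The simulation changed 200 of 15115 genes and used 1 dispersion, whereas 38.4% to 57.6% of genes were called in the pairwise contrasts. Its rates therefore do not give the share of changes missed in these data.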

Other observations

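Of the 488 genes whose values had been shifted in the deposited table, 173 have descriptions that name the mitochondrion. The realignment was chosen only after the data had been seen. After it, 12 of the 173 were higher and 117 lower in OU than in ON (median log2 -0.50), and 5 were higher and 127 lower in PN than in ON (-0.64). From PN to PU 10 were higher and 31 lower (-0.12), and from OU to PU 10 were higher and 86 lower (-0.28). Across all shifted genes 71 were higher and 216 lower in OU minus ON, and 99 and 232 in PN minus ON.

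The chaperone gene hsp-70 differed between libraries of the same group, a feature chosen after its values were seen. Its normalised reads were 12 in PN 1 against 1170.3 in PN 2 and 995 in PN 3. They were 44 to 87.8 in ON, 1023 to 1669 in OU and 6320.2 to 12399 in PU.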
